A study of Homo sapiens with 8 samples.

How the data were processed

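RNA-seq libraries of U2OS cells were analysed from a table of raw counts per gene as the authors deposited it, with 4 libraries of cells overexpressing the C-terminal zinc finger part of ZNF768 for 12 h (ZNF768-DN) and 4 of control cells. Per the labels' protocols, 100 ng of DNase-treated total RNA entered a strand-specific NuGEN kit that primes with selected hexamers and marks the second strand with dUTP, and the libraries were read on an Illumina HiSeq1500 as single reads of 100 bp. Per the submitters' processing notes, BWA, featureCounts and Subread 1.4.6-p3 were used with GRCh38, and the name of the deposited table gives GENCODE release 25 as the annotation of the counts. The order of these tools, their parameters, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts at antisense, overlapping and near-identical genes are therefore uncertain. The columns of the control libraries carry the name WT in the table and were matched to the control samples by that name and their replicate number.

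The table holds 58037 gene rows, with 0 columns outside the 8 libraries. Symbols and coordinates came from GENCODE release 29 on GRCh38 through the gene identifiers, which matched 57388 rows, and 649 rows kept their identifier. GC content and length were those of the longest transcript of each gene, and 99.7% of the tested genes had a value. Library totals were 10205169 to 19608288 counts. A floor of 3 counts covers counting error alone, since reads without molecular identifiers are not independent molecules. Pairs of libraries within a group were compared before averaging, and a chi-square per degree of freedom of 15.5 to 29.6 showed that no library was a copy of another.

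Counts were filtered with filterByExpr and scaled with TMM factors, which left 16869 genes, and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, glmQLFit with robust estimation, glmQLFTest) and BH adjustment over all genes tested. Adjusted p-values of genes in the text come from this test unless another is named. Fold changes of at least 1.5 were tested with glmTreat on the same fit. Normalised read counts are CPM after TMM scaling, log2 fold changes are ZNF768-DN over control, and their standard errors were derived from the fold change and the F statistic. Of 32 gene lists fixed before the data were examined, the 31 with at least 3 tested members were tested two-sided with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 and BH adjustment over the lists. Adjusted p-values of lists come from camera. Measures of single libraries were compared with two-sided exact permutation tests, for which 0.0286 is the smallest p that 4 against 4 libraries allow.

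Genes named in the text followed a rule fixed before the data were examined. It takes ZNF768 and NGFR, then the 12 highest and the 12 lowest log2 fold changes among genes with a symbol that is not a clone name, an FDR under 0.05, a mean of at least 2 CPM and no overlap between the groups. It adds up to 4 members with the smallest p among the changed members of each list called by camera, and up to 3 of the most abundant members of other lists described. HBB and HBD were chosen after their values were seen.

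The alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE factors, library size alone, no filter, a filter of 1 CPM in 4 libraries, mitochondrial and structural small RNA genes left out, a replicate block, each library left out in turn, an estimated correlation for camera, and fry. The removal of GC content and transcript length was added after seeing the data. It fitted natural splines with 5 degrees of freedom to the log deviations of each library and used them as offsets. Similarity of zinc finger genes to the ZNF768 protein was searched with tblastn (BLAST 2.17.0). The tests were tried on simulated data with the means and library sizes of the 16869 genes and 200 changed genes, drawn from those of at least 2 CPM. For ZNF768-DN against control, the quasi-likelihood test found 32.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 7.3% false among its calls. With a GC trend added to the simulated libraries, 69.2% of its calls were false, and 6.6% after the removal of GC content and length. The added trend was linear in GC content, equal in all simulated ZNF768-DN libraries and without a length trend. The removal models such a trend, so the simulation does not show how it does on trends of other forms. Only 200 genes were changed in the simulation, against 5870 called in the data. Its shares of found and false genes therefore need not hold for the data. Other software was R 4.3.3 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.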

Results

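Total RNA of U2OS cells, an established human osteosarcoma line, was sequenced in 8 libraries of 2 groups. In 4 libraries, named ZNF768-DN here, the C-terminal zinc finger part of ZNF768, a transcription factor of the C2H2 zinc finger family, had been overexpressed conditionally for 12 h to block the function of the protein. The other 4 libraries were controls. The control libraries held 14005979, 19608288, 17292246 and 14393136 counts, and the ZNF768-DN libraries held 17086651, 15716048, 14308618 and 10205169. At these depths, a floor of 3 counts lay between 0.153 and 0.294 CPM, the unit of counts scaled to the size of the library. The single comparison asked which transcripts differ between cells with the overexpressed construct and control cells. No induction time is given for the controls, whose columns are named WT. Effects of the vector or of the induction therefore cannot be told apart from those of ZNF768 inhibition. The labels do not say whether the 4 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

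ZNF768 itself was 27.7-fold higher in the ZNF768-DN libraries. Its normalised read count was 27.0 ± 2.17 CPM in control and 747 ± 203 CPM in ZNF768-DN (SD, n = 4 each), a log2 fold change of 4.79 ± 0.19 (SE, adjusted p = 9.24e-11). The gene (ENSG00000169957.9) lies on the minus strand of chromosome 16 from 30524001 to 30526821 in GRCh38, and its count cannot separate the construct from the endogenous transcript. The counts of 4 other zinc finger genes, picked after their values were seen, rose with it. ZNF70 went from 29.7 ± 1.79 to 603 ± 50.3 CPM (chromosome 22, 23738678 to 23751092, minus strand; adjusted p = 3.76e-16), and ZNF71 from 5.54 ± 1.05 to 224 ± 53.8 CPM (chromosome 19, 56595264 to 56626481, plus strand; adjusted p = 4.53e-10). GLI4 (chromosome 8, 143267433 to 143276931, plus strand) went from 7.08 ± 0.722 to 117 ± 9.94 CPM, with a log2 fold change of 4.04 ± 0.12. ZNF629, on chromosome 16 like ZNF768 (30778449 to 30787202, minus strand), went from 37.5 ± 1.04 to 286 ± 41.9 CPM, with one of 2.93 ± 0.12. Zinc finger genes resemble each other in sequence, so the assignment of reads among them is uncertain. NGFR, the nerve growth factor receptor that serves as a surface marker in some expression vectors, rose from 22.7 ± 2.97 to 43.9 ± 7.14 CPM (log2 fold change 0.95 ± 0.14, adjusted p = 1.97e-05). HBD and HBB, the delta and beta globin genes on chromosome 11, were singled out after their values were seen. HBD went from 838 ± 206 to 3770 ± 609 CPM and HBB from 83.3 ± 19.7 to 364 ± 53.1 CPM, with log2 fold changes of 2.17 ± 0.16 and 2.13 ± 0.16.

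**Figure D1:**
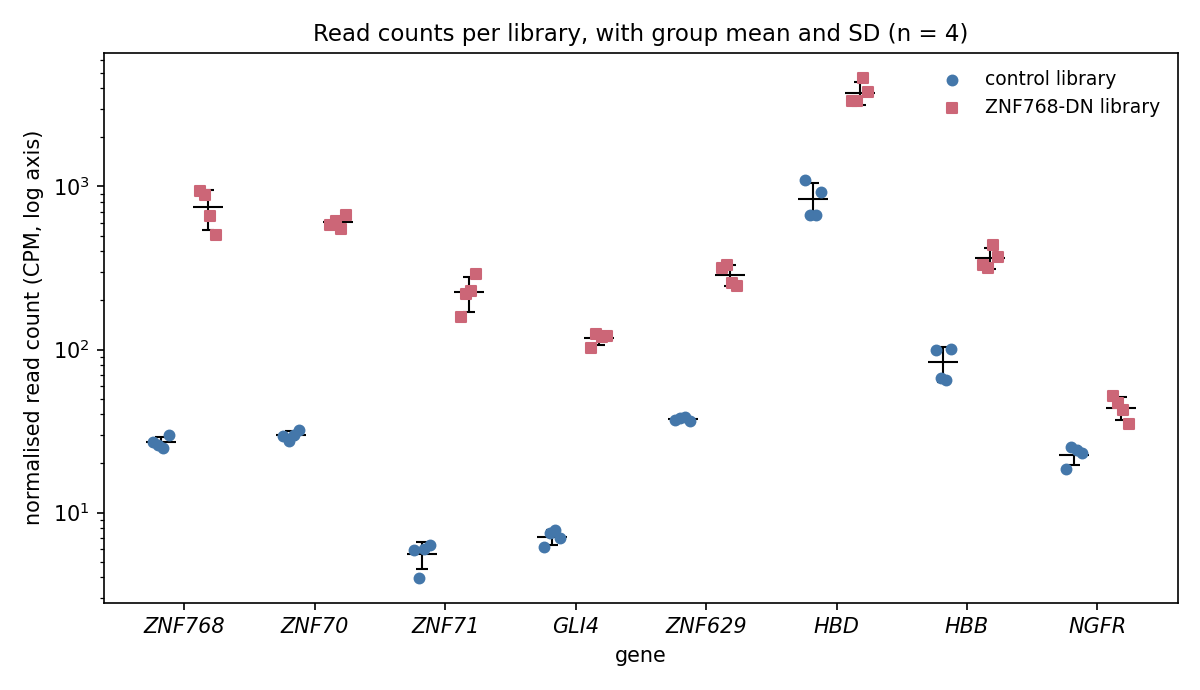
Normalised read counts (CPM, log axis) of 8 genes in each of the 4 control libraries (circles) and the 4 ZNF768-DN libraries (squares), with the mean and SD of each group. For every gene drawn, the ZNF768-DN libraries lie above the control libraries, by 27.7-fold on average for ZNF768.

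Of 16869 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg (BH) adjustment, 5870 (34.8%) changed at an FDR of 5%. Of these, 2698 were higher and 3172 lower in ZNF768-DN, and the median size of the change was 0.61 on the log2 scale. With scaling to library size alone, 1060 were higher and 4574 lower, and the median log2 fold change of all genes was -0.18 in place of 0.02. A change beyond 1.5-fold was shown for 739 genes, 85 higher and 654 lower. Across 10735 protein-coding genes, which are not independent replicates, the fold change followed the sequence of the transcript, with a Spearman correlation of 0.58 with GC content and -0.46 with transcript length. In the decile of these genes with the lowest GC content the median log2 fold change was -0.50, and in the decile with the highest it was 0.28. With GC content and transcript length removed per library, an alternative chosen after seeing the data, 3721 genes changed, 2030 higher and 1691 lower, and 99 passed the 1.5-fold test. Of the 3721 genes, 2628 had changed in the same direction before the removal. Slopes with GC content and length were fitted to the deviations of each library from the mean of the 8 libraries, so their signs are relative. Of 7 library measures, 4 separated the groups, each with an exact permutation p of 0.0286, the smallest possible here, and 0.05 with BH adjustment. They were the slope with GC content, the slope with length (0.093 ± 0.051 and -0.093 ± 0.026 log2 units per doubling; SD, n = 4 each), the protein-coding share of counts (71.0% ± 0.695 and 67.8% ± 1.60) and the TMM factor (1.069 ± 0.0083 and 0.936 ± 0.030). ZNF768-DN replicate 4 stood apart from the other libraries on the first axis of a multidimensional scaling of the libraries, at 2.02 against values from -0.83 to 0.37, and had the fewest counts; without it 5845 genes changed.

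**Figure D2:**
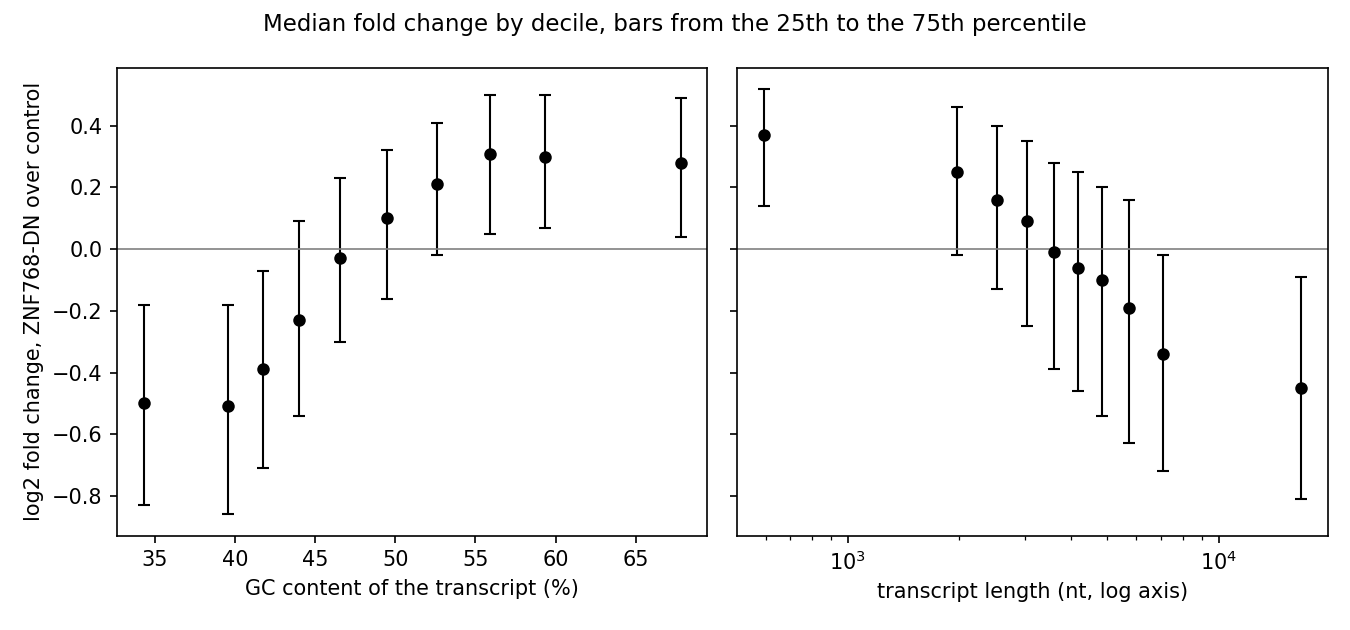
Median log2 fold change of ZNF768-DN over control in each decile of 10735 protein-coding genes ordered by GC content (left, percent) and by transcript length (right, nt, log axis), with bars from the 25th to the 75th percentile of the genes. The median went from -0.50 to 0.28 with GC content and from 0.37 to -0.45 with length.

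Among the highest rises were also short genes of structural RNA families. The U6 small nuclear RNA pseudogene RNU6-37P had a log2 fold change of 5.11 ± 0.69. RNU6-11P was at 0.0963 CPM in control, below the floor, and at 7.32 ± 6.62 CPM in ZNF768-DN, so that its fitted log2 fold change of 6.24 is no exact value; it was 7.32 without control replicate 1 and 5.41 without ZNF768-DN replicate 4. The 5S ribosomal RNA pseudogenes RNA5SP530, RNA5SP318, RNA5SP202 and RNA5SP283 had log2 fold changes of 4.12, 3.54, 3.30 and 3.23. That of RNA5SP318 was 4.39 without control replicate 2, and that of RNA5SP202 was 2.62 without ZNF768-DN replicate 3. Each of these families has many near-identical copies in the genome, so the assignment of reads to a single copy is uncertain. SELPLG, which encodes the P-selectin ligand of leukocytes, rose from 0.825 ± 0.359 to 5.76 ± 0.953 CPM (adjusted p = 2.51e-06). At the other end, the long noncoding RNA TUG1 fell from 134 ± 12.7 to 36.5 ± 5.47 CPM (log2 fold change -1.88 ± 0.12, adjusted p = 1.23e-09), and TGFB2, a ligand of the TGF-beta receptors, from 33.5 ± 2.62 to 8.82 ± 0.547 CPM (-1.93 ± 0.13, adjusted p = 3.54e-09). ASPM, a protein of the mitotic spindle poles, fell from 86.8 ± 13.2 to 23.4 ± 3.51 CPM. The small GTPase gene RAB40C, the transcription factor gene ZBTB26, TIGD7 and C18orf54 fell as well, with log2 fold changes of -1.98, -1.89, -1.93 and -2.18. The RANBP2-like genes RGPD5, RGPD8, RGPD3, RGPD1 and RGPD2 had log2 fold changes of -3.52, -2.37, -2.10, -2.08 and -2.04, and since they are near-identical copies of each other their separate values are uncertain. That of RGPD5 was -4.17 without ZNF768-DN replicate 1. The call of RGPD2 was lost without ZNF768-DN replicate 1 (adjusted p = 0.0743), without ZNF768-DN replicate 4 (adjusted p = 0.0506), with GC content and length removed (adjusted p = 0.0828) and with limma-voom (adjusted p = 0.0588).

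Of 31 gene lists fixed before the data were examined and tested with limma's camera, 14 changed, 10 upwards and 4 downwards. With a correlation estimated for each list in place of the preset 0.01, camera called 0 lists after adjustment, 5 at an unadjusted p under 0.05, and fry called 22. The lowest adjusted p was 0.204 with an estimated correlation.

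Genes of G2 and mitosis fell as a group (adjusted p = 1.68e-05, and adjusted p = 0.204 with an estimated correlation). Of 35 tested members 19 were lower, 5 higher and 11 did not pass; adjusted over the list alone, 19 were lower and 6 higher. CENPF, a protein of the kinetochore, fell from 137 ± 11.3 to 37.9 ± 3.03 CPM (log2 fold change -1.85 ± 0.11, adjusted p = 2.36e-10). CKAP2L and ANLN, both needed for cell division, fell with log2 fold changes of -1.68 and -1.36. DNA repair genes also fell (adjusted p = 0.00221, and adjusted p = 0.264 with an estimated correlation), with 18 of 40 lower and 4 higher, and 19 and 6 adjusted over the list alone. Among them, the homologous recombination gene BRCA1 fell from 38.1 ± 4.07 to 14.2 ± 1.93 CPM (adjusted p = 1.95e-07), and the checkpoint kinase gene ATR and RAD50 with log2 fold changes of -1.35 and -1.12. The median GC content was 43.2% in the G2/M list and 44.1% in the DNA repair list. With GC content and length removed, the G2/M list kept its call (adjusted p = 1.02e-06, and adjusted p = 0.0235 with an estimated correlation), and the DNA repair list did not (adjusted p = 0.0718). The log2 fold changes of ASPM, CENPF, ATR and RAD50 were then -1.15, -1.18, -0.68 and -0.51. The G1/S list did not pass (adjusted p = 0.586), with 10 of 43 members higher and 15 lower, and 11 and 15 adjusted over the list alone, and passed downwards without a low-count filter (adjusted p = 0.0453). Of its most abundant members, the ribonucleotide reductase gene RRM2 fell (log2 fold change -0.67, adjusted p = 2.28e-04), while PCNA and MCM4 had log2 fold changes of 0.02 ± 0.10 and -0.13 ± 0.11 and did not pass, although MCM4 passed with library size alone (adjusted p = 0.0275).

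Targets of p53 rose (adjusted p = 0.0375, and adjusted p = 0.204 with an estimated correlation). Of 35 members 13 were higher and 5 lower, and 16 and 6 adjusted over the list alone. SESN2, a stress-induced regulator of mTORC1, rose from 50.7 ± 1.16 to 81.2 ± 7.27 CPM (adjusted p = 3.4e-05), and CYFIP2 and FDXR by 0.53 and 0.65 on the log2 scale, while RRM2B, a ribonucleotide reductase subunit, fell from 111 ± 11.7 to 52.2 ± 6.13 CPM (adjusted p = 4.7e-07). The call of the list was lost without control replicate 1 (adjusted p = 0.0634), without ZNF768-DN replicate 4 (adjusted p = 0.0697) and with scaling to library size alone (adjusted p = 0.104). It held with GC content and length removed (adjusted p = 0.0402, and adjusted p = 0.184 with an estimated correlation).

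Of 60 cytosolic ribosomal protein genes 50 were higher and 0 lower, also adjusted over the list alone, with a median log2 fold change of 0.52 (adjusted p = 7.63e-17, and adjusted p = 0.204 with an estimated correlation). RPL8 went from 1649 ± 218 to 2590 ± 167 CPM, RPL19 from 673 ± 80.4 to 1090 ± 64.0 CPM, and RPL29 and RPLP2 rose by 0.72 and 0.60 on the log2 scale. With GC content and length removed, 31 of the 60 were higher and 0 lower, and the list kept its call (adjusted p = 7.16e-10, and adjusted p = 0.207 with an estimated correlation), but RPL8, RPL29 and RPLP2 lost theirs (adjusted p = 0.0882, 0.161 and 0.59). Nuclear genes of the respiratory chain rose likewise (adjusted p = 7.24e-09, and adjusted p = 0.212 with an estimated correlation), with 30 of 48 higher and 0 lower, and 34 and 1 adjusted over the list alone. Among them were UQCRQ, UQCRC1 and CYC1 of complex III, with log2 fold changes of 0.73 ± 0.12, 0.65 ± 0.11 and 0.59 ± 0.11, and COX6A1 of complex IV, with 0.86 ± 0.14. Of 18 glycolysis genes 12 were higher and 1 lower, also adjusted over the list alone (adjusted p = 9.1e-05, and adjusted p = 0.204 with an estimated correlation). ALDOA rose from 773 ± 40.3 to 1181 ± 107 CPM, and ALDOC, ENO2 and TPI1 by 0.92, 0.61 and 0.68 on the log2 scale. The protein-coding genes of the mitochondrial genome rose (adjusted p = 0.00521, and adjusted p = 0.264 with an estimated correlation), with 5 of 13 higher and 1 lower, and 6 and 1 adjusted over the list alone, among them MT-ND4 (log2 fold change 0.49 ± 0.10, adjusted p = 0.001). This call was lost with GC content and length removed (adjusted p = 0.141). The nuclear respiratory chain list kept its call after the removal, with 21 members higher and 0 lower (adjusted p = 1.09e-05, and adjusted p = 0.207 with an estimated correlation). So did the glycolysis list, with 7 higher and 1 lower (adjusted p = 0.00444, and adjusted p = 0.109 with an estimated correlation). Median transcript lengths were 1864.5 nt for ribosomal proteins, 1511.5 nt for nuclear respiratory chain genes and 784 nt for mitochondrially encoded genes, and the median GC content of glycolysis genes was 53.2%. The share of counts at the mitochondrial ribosomal RNA genes was 21.4% ± 1.06 in control and 23.9% ± 1.70 in ZNF768-DN (SD, n = 4 each), a difference that did not pass a two-sided exact permutation test (p = 0.0857, and 0.12 with BH adjustment over 7 library measures).

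Immediate early genes, which respond within minutes to growth factors and stress, rose (adjusted p = 0.00195, and adjusted p = 0.204 with an estimated correlation), with 10 of 29 higher and 1 lower, also adjusted over the list alone. EGR1 rose from 141 ± 5.34 to 327 ± 22.4 CPM (adjusted p = 5.73e-08), FOS from 5.86 ± 1.25 to 16.3 ± 2.47 CPM (adjusted p = 3.62e-06) and NR4A1 from 15.6 ± 2.85 to 33.9 ± 6.10 CPM, while KLF6 fell (log2 fold change -0.90). Of 30 ATF4 targets, genes of the integrated stress response, 12 were higher and 4 lower, and 14 and 4 adjusted over the list alone (adjusted p = 0.0116, and adjusted p = 0.264 with an estimated correlation). PPP1R15A, a phosphatase subunit that reverses that response, rose from 55.2 ± 5.09 to 104 ± 21.3 CPM, as did SESN2, while ALDH1L2 and CEBPG fell, with log2 fold changes of -1.59 and -0.93. With GC content and length removed, both lists, of median GC content 55.9% and 52.5%, lost their calls (adjusted p = 0.165 for immediate early genes and 0.141 for ATF4 targets). Targets of SRF and genes of the actin cytoskeleton rose (adjusted p = 8.44e-04, and adjusted p = 0.204 with an estimated correlation), with 11 of 23 higher and 1 lower, and 12 and 1 adjusted over the list alone, at a median GC content of 55.3%. MYL9, ZYX, ACTB and TAGLN2 had log2 fold changes of 0.62, 0.59, 0.59 and 0.57, and TAGLN2 was not called with GC content and length removed (adjusted p = 0.209). The list of SRF targets and actin genes kept its call after that removal (adjusted p = 0.0111, and adjusted p = 0.214 with an estimated correlation). YAP and TEAD targets fell (adjusted p = 0.0375, and adjusted p = 0.327 with an estimated correlation), with 7 of 20 lower and 0 higher, and 7 and 1 adjusted over the list alone. Next to TGFB2, FJX1 fell from 17.0 ± 2.19 to 9.33 ± 2.91 CPM, ANKRD1 from 260 ± 24.95 to 189 ± 11.1 CPM, and DOCK5 had a log2 fold change of -0.67, which was not called with GC content and length removed (adjusted p = 0.262). The call of the list was lost without control replicate 2 (adjusted p = 0.0806), control replicate 3 (0.0511) or ZNF768-DN replicate 4 (0.052), and with the stricter filter (0.0507). It held with GC content and length removed (adjusted p = 0.0136, and adjusted p = 0.207 with an estimated correlation).

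The list of C2H2 zinc finger genes, which holds ZNF70, ZNF71 and ZNF629 but not ZNF768 or GLI4, fell. Of 469 tested members 187 were lower and 19 higher, and 196 and 23 adjusted over the list alone, with a median log2 fold change of -0.49 (adjusted p = 5.23e-07, and adjusted p = 0.204 with an estimated correlation). ZNF638 fell from 174 ± 12.6 to 76.1 ± 11.03 CPM (adjusted p = 2.41e-07). The median GC content of the list was 43.5%. With GC content and length removed, 91 members were lower and 22 higher, and the call held (adjusted p = 2.04e-04, and adjusted p = 0.0235 with an estimated correlation). Replication-dependent histone genes were called upwards (adjusted p = 0.0126, and adjusted p = 0.582 with an estimated correlation), with 5 of 47 higher and 0 lower, and 1 and 0 adjusted over the list alone. HIST1H2BK rose from 338 ± 59.7 to 553 ± 132 CPM (adjusted p = 0.00312). HIST1H3A, HIST1H2AC and HIST1H4H rose as well (adjusted p = 0.0224, 0.025 and 0.0357). The calls of HIST1H2AC and HIST1H4H were lost with library size alone (adjusted p = 0.297 and 0.463), among other settings. With GC content and length removed, HIST1H2BK and HIST1H3A were not called (adjusted p = 0.758 and 0.441), while HIST1H2AC and HIST1H4H were (0.00407 and 0.0088). That removal turned the direction of the list, whose median transcript length was 648 nt, with 2 members higher and 11 lower (adjusted p = 0.0402, and adjusted p = 0.456 with an estimated correlation), and the call was lost without control replicate 3 (adjusted p = 0.0727). Of 10 tested markers of B cells and leukocytes 4 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0375, and adjusted p = 0.204 with an estimated correlation). They stayed at low levels, as LCP1 with 4.86 ± 0.73 and 8.91 ± 2.04 CPM and CD22 with 9.17 ± 2.35 and 13.9 ± 0.703 CPM. CD22 was not called with library size alone (adjusted p = 0.0724) or with GC content and length removed (0.0903). The call of the list was lost without control replicate 1, 2 or 3 (adjusted p = 0.0625, 0.0929 and 0.0511), without ZNF768-DN replicate 4 (0.0652) and with GC content and length removed (0.12). Epithelial markers did not pass as a list (adjusted p = 0.118), although KRT8 and KRT18, which overlap each other on opposite strands, were higher by 0.62 ± 0.10 and 0.60 ± 0.12, as 2 of 6 tested members, also adjusted over the list alone.

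**Figure D3:**
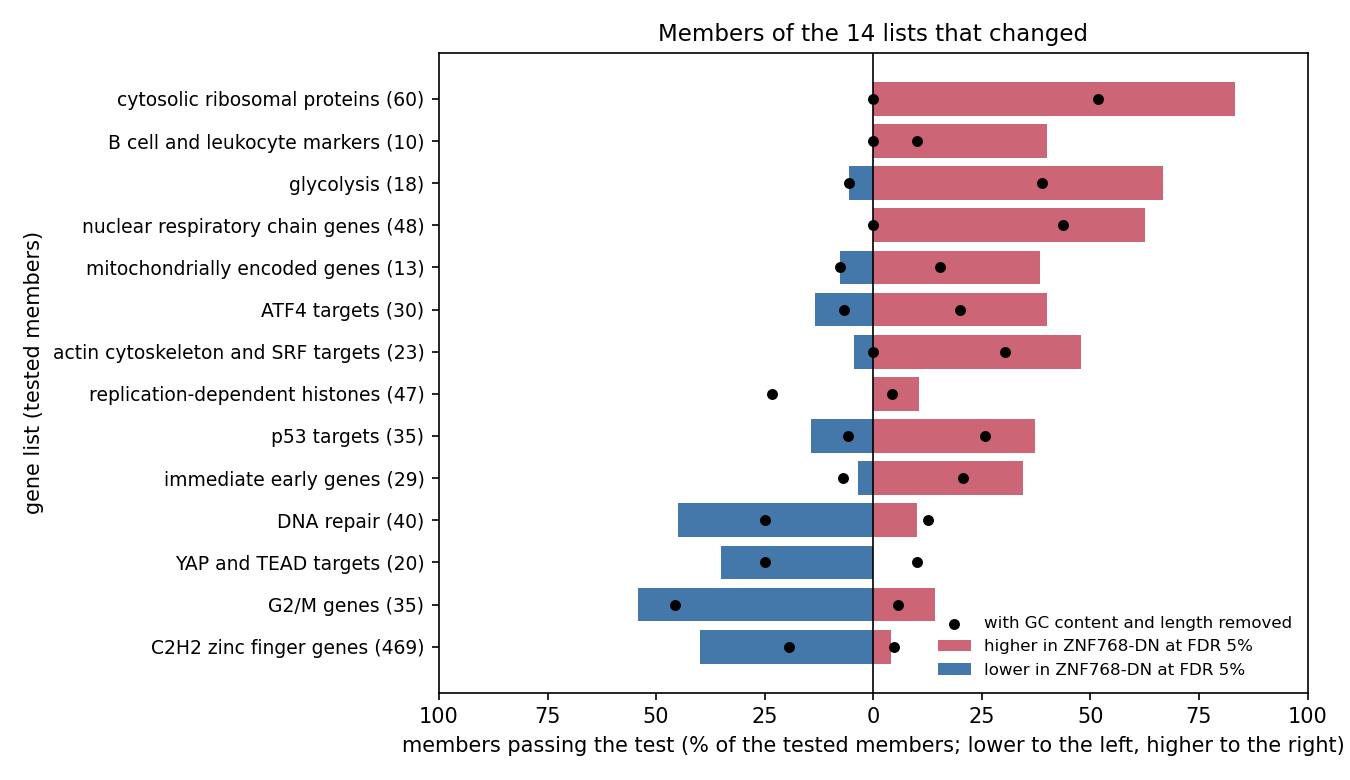
Share of the tested members of each of the 14 changed lists (percent) that were higher (bars to the right) or lower (bars to the left) in ZNF768-DN at an FDR of 5%, with points for the same shares after GC content and transcript length were removed. For cytosolic ribosomal proteins 50 of 60 members were higher, and after the removal 31. For histones 0 members were lower before the removal and 11 after it.

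Among the lists that did not pass, 2 did so with GC content and length removed. WNT targets (adjusted p = 0.284), with 0 of 14 higher and 2 lower, also adjusted over the list alone, passed downwards after the removal (adjusted p = 0.0151, and adjusted p = 0.171 with an estimated correlation). They also passed without a low-count filter (adjusted p = 0.0462). NF-kB and inflammatory genes did not pass (adjusted p = 0.0671), with 5 of 19 higher and 1 lower, also adjusted over the list alone. The NF-kB list passed upwards after the removal (adjusted p = 0.0485, and adjusted p = 0.207 with an estimated correlation) and with the replicate block (adjusted p = 0.0459). Of its most abundant members, the NF-kB subunit gene NFKB2 rose from 44.2 ± 2.21 to 77.6 ± 7.51 CPM (adjusted p = 6.3e-06), the matrix protease gene MMP3 fell (log2 fold change -0.33, adjusted p = 0.0171), and NFKB1 had a log2 fold change of 0.20 ± 0.13 and did not pass. The call of MMP3 was lost without control replicate 2 (adjusted p = 0.0587) or ZNF768-DN replicate 1 (0.0551), and with the replicate block (0.0554). Heat shock genes did not pass (adjusted p = 0.777), with 7 of 19 higher and 5 lower, and 7 and 6 adjusted over the list alone. The chaperone gene HSP90AA1 fell from 973 ± 13.9 to 512 ± 31.6 CPM (adjusted p = 8.41e-07), HSPA8 had a log2 fold change of 0.23 ± 0.11 and did not pass except with DESeq2 (adjusted p = 0.045), and HSP90AB1 had one of 0.29 ± 0.10 (adjusted p = 0.0392). The last call was lost without control replicate 1 (adjusted p = 0.0634), 2 (0.101) or 3 (0.122), and without ZNF768-DN replicate 1 (0.0844), 3 (0.0737) or 4 (0.0998). It was also lost with library size alone (0.544), without a low-count filter (0.159), with the replicate block (0.117) and with GC content and length removed (0.128). Interferon-stimulated genes did not pass (adjusted p = 0.491), with 4 of 30 higher and 9 lower, and 5 and 12 adjusted over the list alone. PARP14 fell from 93.7 ± 6.77 to 43.4 ± 9.02 CPM (adjusted p = 2.56e-06). Genes of RNA polymerase II transcription did not pass (adjusted p = 0.842), with 17 of 50 higher and 18 lower, and 18 and 19 adjusted over the list alone. The elongation factor gene SUPT6H rose (log2 fold change 0.48, adjusted p = 0.00146), AFF4 of the super elongation complex fell (log2 fold change -0.67, adjusted p = 1.96e-04, and 0.904 with GC content and length removed), and SSRP1 had a log2 fold change of 0.27 ± 0.12 and did not pass. SSRP1 passed with GC content and length removed (adjusted p = 0.026), with DESeq2 (0.0445) and without ZNF768-DN replicate 3 (0.033).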

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

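The 91 genes checked and 7 measures of the libraries were searched for single libraries far from the other 3 of their group. Of 196 groups of 4 values, 11 held such a library, and chance alone gives about 1 in 20, which is 9.8 here. No explanation was tested for these values.

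The TMM factor of ZNF768-DN replicate 4, the library with the fewest counts, was 0.981, against 0.917 to 0.924 in the other ZNF768-DN libraries. The U6 pseudogene RNU6-11P stood at 17.2 CPM in the same library and at 3.2 to 5.31 CPM in the other ZNF768-DN libraries. RNU6-37P was at 0.656 CPM in control replicate 4, with 0.332 to 0.385 CPM in the other controls.

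ZNF71 was lowest in control replicate 2, with 3.99 CPM against 5.91 to 6.3 CPM in the other controls. Control replicate 4 had the lowest values of CENPF (120 CPM, against 141 to 144) and of NFKB2 (40.9 CPM, against 45.0 to 45.5).

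In ZNF768-DN replicate 1, EGR1 was at 293 CPM (against 335 to 341 in the other ZNF768-DN libraries), UQCRQ at 194 CPM (against 234 to 241) and MYL9 at 83.3 CPM (against 101.6 to 102). In ZNF768-DN replicate 2, NR4A1 was at 43.0 CPM (against 30.2 to 31.4) and UQCRC1 at 162 CPM (against 134 to 138). Each of the 10 genes was called in the same direction without the library named.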

How the results depend on the processing

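Of the alternatives, only the removal of GC content and transcript length was chosen after seeing the data. It gave 3721 changed genes (2030 higher and 1691 lower) and 99 past 1.5-fold. Under the other settings, 4548 to 6207 genes changed. Scaling to library size alone gave 1060 genes higher and 1461 past 1.5-fold, where the median of all genes moved to -0.18. The log2 fold change of ZNF768 lay between 4.53 and 4.95 and was called throughout. Leaving out 1 library at a time gave 495 to 781 genes past 1.5-fold and 11 to 14 lists. Camera with an estimated correlation called 0 lists, 5 at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 22. Of 90 genes checked, 68 kept direction and call under every setting that tested them.

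The replicate block gave 4914 changed genes, 2088 higher and 2826 lower, 600 past 1.5-fold and 15 lists. Deviations of libraries with the same number correlated at -0.29, 0.05, -0.12 and -0.08, so no shared deviation was seen. Whether the numbers mark a shared culture or day is not given.

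The histone list, called upwards, was called downwards with GC content and length removed (median -0.0409, adjusted p = 0.0402, and adjusted p = 0.456 with an estimated correlation). The other reversals were of results that did not pass, and the cause was not tested. For lists they are of the direction of the test, and the median printed may keep its sign. With GC content and length removed, PCNA went to -0.081 and the medians were -0.0798 for heat shock genes, -0.102 for ribosome biogenesis, 0.16 for hypoxia genes, -0.146 for TGF-beta targets, 0.0595 for osteoblast genes and 0.0904 for apoptosis. With library size alone, PCNA went to -0.172, ribosome biogenesis to -0.139, TGF-beta targets to -0.255, osteoblast genes to -0.226 and RNA polymerase II transcription to -0.041. Without a filter, PCNA went to -0.039, ribosome biogenesis to -0.00739, TGF-beta targets to -0.128, and RNA polymerase II transcription, with a median of 0.0942, was tested downwards. G1/S genes, endoplasmic reticulum chaperones and WNT targets passed downwards there (adjusted p = 0.0453, 0.0153 and 0.0462). The stricter filter gave -0.0377 for osteoblast genes. Fry turned the direction of the test, at the same medians, for heat shock genes (0.187), ribosome biogenesis (0.0509), TGF-beta targets (-0.0625), osteoblast genes (-0.0393) and RNA polymerase II transcription (0.153). Leaving out 1 library gave ranges of -0.012 to 0.086 for PCNA, -0.0317 to 0.098 for ribosome biogenesis, -0.00584 to 0.14 for hypoxia genes, -0.131 to -0.0158 for TGF-beta targets, -0.128 to 0.0181 for osteoblast genes and -0.0826 to 0.154 for metallothioneins.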

Other observations

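Classes of short or noncoding transcripts were counted beside all 16869 genes, of which 2698 were higher and 3172 lower. Of 1082 processed pseudogenes tested, 172 were higher and 30 lower in ZNF768-DN, with a median log2 fold change of 0.40. After the removal of GC content and length 29 were higher and 33 lower. Of 105 genes of the class misc_RNA 18 were higher and 0 lower, and 1 and 0 after the removal. Of 17 ribosomal RNA pseudogenes 9 were higher and 0 lower, and of 33 small nuclear RNA genes 7 were higher and 0 lower; after the removal these counts were 4 and 0 and 7 and 0. Of 60 sense intronic transcripts 11 were lower and 0 higher, and 7 and 0 after the removal. Many pseudogenes share reads with their parent genes, and no class was tested as a group.

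The test of genes past 1.5-fold by GC content, the tests of single zinc finger genes and the test of the globin ratio within the groups were chosen after the result was seen, and so were the zinc finger and globin genes weighed here. All 35 splits of the 8 libraries into 4 and 4 were refitted. The real split was the 1 with as many changed genes (5870 against at most 1 in the others), as many higher (2698 against 1), as many lower (3172 against 1) and as many past 1.5-fold (739 against 1). All other splits mix the groups, so a group difference adds to their spread and leaves few calls. The lowest share that the splits allow is 1 of 35, so these counts argue against chance only to that limit. For the changed lists the real split was also 1 of 35, but with a small margin (14 against 11). Single lists can be called by chance, since a split with 2 libraries of either group on each side and 0 changed genes called 6 lists, and camera with an estimated correlation called 0 lists in the real split, 5 at an unadjusted p under 0.05, where fry called 22.

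The first pattern is the rise of ZNF70, ZNF71, GLI4 and ZNF629 with ZNF768. Of the 4 genes, 0 share an exact stretch of 50 nt with a ZNF768 transcript. Their longest shared stretches are 35 nt for ZNF70, 19 nt for GLI4, 35 nt for ZNF629 and 23 nt for ZNF71. Among all 470 zinc finger genes compared, 0 share a stretch of 50 nt, so the outcome would have been the same for any of them. The test therefore does not decide on reads of the native ZNF768 sequence, since the treatment of inexact matches is not given. Reads of a construct counted at a gene should keep 1 ratio to ZNF768, which is argued against for ZNF71, whose ratio went from 16.8 to 57.2% over the ZNF768-DN libraries, a spread at percentile 96.0 among 200 genes of like abundance (90 to 97.5 with 1 library left out). For ZNF629 the ratio varied less than for most such genes (33.4 to 48.5%, percentile 3.5, and 3.0 to 10.0 with 1 library left out). It was still not steady, with a chi-square per degree of freedom of 53.8, against a median of 213.4 for the genes of like abundance. The test therefore does not decide on construct reads for ZNF629. For ZNF70 (61.7 to 132.4%, percentile 69.0, but 26.0 without ZNF768-DN replicate 4) and GLI4 (10.9 to 23.9%, percentile 70.5, but 47.5 without ZNF768-DN replicate 1), and for the 4 genes together (median 69.8), construct reads and regulation cannot be told apart. A construct with altered codons also stays open, also for ZNF71. In tblastn similarity to the ZNF768 protein the median percentile among 470 zinc finger genes was 91.8. It was 87.0 for ZNF70, 96.6 for ZNF71 and 100.0 for ZNF629, but 35.8 for GLI4. Regulation by the construct stays open as well and was not tested. For each of the 4 genes the ratio to ZNF768 rose from ZNF768-DN replicate 1 to 4, while ZNF768 fell from 940 to 505 CPM. The results for the single genes are therefore not independent.

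The second pattern is the rise of HBB and HBD. RNA of erythroid cells is argued against, since the alpha globin genes HBA1 and HBA2 held 2 counts in the ZNF768-DN libraries, 9.17e-04% of the counts of HBB and HBD. A single transcript of another origin, such as a vector with globin sequence, may be counted at both genes. The ratio of HBD to HBB varied little within the control libraries (9.09 to 10.96, percentile 7.5 among 2000 pairs of genes of like abundance) and within the ZNF768-DN libraries (10.02 to 10.63, percentile 1.85), and at percentile 1.0 over both groups. These pairs were drawn by abundance alone, so a steady ratio does not tell a single transcript from joint regulation of both genes. HBD was at 838 ± 206 CPM already in control. The spread of the ratio over all 8 libraries, at percentile 0.25, decides nothing, since the genes were chosen for their shared rise. Of the other genes of the beta globin locus, HBE1 held 155 raw counts in the control libraries and 301 in the ZNF768-DN libraries. HBG2 held 6 and 17, and HBG1 held 2 and 0. A change in transcription of the beta globin locus stays open and was not tested.

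The third pattern is the dependence of fold change on GC content and transcript length. Control libraries had slopes of -0.171 to -0.077 log2 units per 10% GC, and ZNF768-DN libraries 0.094 to 0.217 (exact permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.05 with BH adjustment over 7 measures). These slopes are of deviations from the mean of the 8 libraries. Only their difference between the groups is measured, and not the bias of either group by itself. After the removal of a GC and length dependent difference between libraries 3721 genes passed, 63.4% of the earlier number of 5870. Of the 3721 genes, 2628 had passed in the same direction before. The fitted trend thus does not account for the calls of these 2628 genes. A difference of another form is not covered, since the removal used the longest transcript of each gene and turned the direction of the histone list. For the other genes called before, a GC and length dependent difference stays open. The same holds for the genes past 1.5-fold, of whose number 13.4% passed after the removal. The slopes separate the groups. A library bias therefore cannot be told apart from effects of ZNF768 inhibition, the construct or its induction on GC-poor and long transcripts.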
